A study of Mus musculus with 3 samples.

How the data were processed

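The series holds 3 samples of primary mouse embryonic fibroblasts: a CAP-D3 ChIP from Rb+/+ cells, a CAP-D3 ChIP from RbΔL/ΔL cells, and input DNA. Per the labels' protocols, ChIP libraries were built with a commercial ChIP-seq kit and sequenced as paired ends on an Illumina instrument. The antibody was raised against a fragment of CAP-D3. Per the submitters' processing notes, Bowtie 1.0 and MACS 1.4.2 were used and the genome build was mm9. The parameters, the control library given to the peak caller and the treatment of duplicate reads and of reads that map to several places are not given in the sources used here. Each can change which weak peaks and which repeat regions are listed.

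The deposited files are 1 list of peaks per ChIP library, so the authors called peaks per sample and not on pooled samples. Each line holds a chromosome, a start, an end, a peak name and a score. The score was given to each peak by the authors' peak caller, and the deposited scores start at 50.02 in both lists. The files do not say what the score measures. MACS of this generation writes a multiple of the negative log10 of a p-value, and the lowest score has that form, but no header states it. In the report, scores were therefore used to rank, band and filter peaks within a list, and to correlate ranks across pairs of overlapping peaks. In the closing section, repeated score values were also fitted as Poisson tails, under the assumption that the score has this form. No values of the input library were analysed here, and the read depth of the libraries is unknown.

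The files' coordinates were checked against the chromosome lengths of mm9 held in the GenomeInfoDb package (version 1.38.1). All 20 chromosomes ended within the mm9 lengths, and peaks on 7 chromosomes lay beyond the ends of the later mm10 build. Starts are given 1-based. The gene table at hand belongs to a later build and was not used. The planned comparisons with gene features, with fixed gene lists and with sequence content were therefore not run.

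Peaks were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks were called overlapping when they shared at least 1 bp. Chance overlap came from 1000 random placements of the other list, each peak keeping its width and chromosome and lying between the lowest and the highest position listed for that chromosome in either list. Density per chromosome used full mm9 lengths. The centromeric zone was 3 to 8 Mb of each chromosome, since the assembly has no sequence before about 3 Mb, and the distal zone was the last 5 Mb. Zone densities were divided by the density expected from the length of the zones (3.88% of the sequence from 3 Mb on). Peaks within 10 kb of another peak of the same list were called clustered. Counts have exact Poisson intervals, shares have exact (Clopper-Pearson) binomial intervals, and differences of shares have Newcombe intervals, all at 95%. Sequencing reads and neighbouring peaks are not independent molecules, so intervals cover counting error only. With 1 library per genotype no p-value was computed. The peaks named are the 5 highest-scoring ones shared by both lists, ranked in each list, and the 5 highest-scoring ones found in each list alone. This rule and the alternatives were written before the data were examined, apart from the score bands, the local shift of 20 to 200 kb, the peaks left unmatched at a score of 200 or more, the pairs of peaks, the counts per megabase (added after the data were seen, with the bounds for their correlations set before those were computed), and the regions of chromosomes 2, 9 and 17.

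The overlap and clustering code was tested on simulated data. With 10.0%, 30.0% and 70.0% of 8195 simulated Rb+/+ peaks given a partner, it recovered 10.2%, 30.1% and 70.1%. With 9.31% of 8595 simulated peaks made members of pairs 3 kb apart, the number of clustered peaks rose by 9.01% of the list, since some of them already lay near another peak. Alternatives were a minimum score of 100, lists of equal length, other definitions of overlap, merged peaks, circular or local shifts, other zone widths and other clustering distances.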

Results

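Binding of CAP-D3 to the genome was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in primary mouse embryonic fibroblasts at passage 4. CAP-D3 is a non-SMC subunit of condensin II, a complex that compacts and shapes chromosomes. One ChIP library came from Rb+/+ cells and 1 from cells homozygous for the RbΔL allele, which encodes a retinoblastoma protein with a mutated LXCXE-binding cleft, the surface through which it contacts many chromatin proteins. An input DNA sample completed the 3 samples, and no values of it were analysed here. The comparison asks where CAP-D3 is found in each genotype. The values are 1 list of called peaks per ChIP library. The number of reads behind each list is unknown, and there were no replicate libraries, so the comparisons below describe these libraries and no test of genotype was possible. Intervals are exact 95% intervals unless stated otherwise and cover counting error only. All positions are mm9. No gene annotation of that build was used here, so regions are named by position, and whether they are genic, exonic or intronic was not determined.

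The Rb+/+ list held 8195 CAP-D3 peaks and the RbΔL/ΔL list 6437, a ratio of 1.27. Peaks covered 3573195 bp in Rb+/+ and 2645762 bp in RbΔL/ΔL cells. They were narrow in both, with a median width of 428 bp (quartiles 364 and 476) in Rb+/+ and 412 bp (quartiles 339 and 469) in RbΔL/ΔL. Only 24 Rb+/+ and 11 RbΔL/ΔL peaks were wider than 1 kb. Each peak carries a score from the authors' peak caller, which ranks peaks within a list. Most peaks lay close to the lowest score listed, 50.02 in both lists. The median score was 62.19 in Rb+/+ and 65.68 in RbΔL/ΔL, and 1040 Rb+/+ peaks (12.7%) and 842 RbΔL/ΔL peaks (13.1%) reached a score of 100. The ratio of peak numbers was 1.24 at that minimum, but an equal score need not stand for equal evidence in both lists. Without replicate libraries or read totals, it is not known whether this difference exceeds the spread between libraries of one genotype.

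The strongest CAP-D3 sites were listed in both genotypes, and most of the weak ones in 1 of the lists alone. Of the Rb+/+ peaks, 1066 (13.01%, interval 12.3 to 13.8%) overlapped a RbΔL/ΔL peak by at least 1 bp. Of the RbΔL/ΔL peaks, 1068 (16.6%, interval 15.7 to 17.5%) overlapped a Rb+/+ peak. Random placement of the other list on the same chromosomes gave a mean of 0.223% for Rb+/+ and 0.287% for RbΔL/ΔL peaks over 1000 placements, with highest values of 0.390% and 0.544%. The observed overlap was 58.4 times and 57.9 times these means. When each peak of the other list was instead moved by 20 to 200 kb, which keeps it in its own neighbourhood, the means were 0.393% and 0.499%.

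Overlap rose with the score of the peak. All of the 100 highest-scoring peaks of each list overlapped a peak of the other, which allows a share as low as 96.4%. Among Rb+/+ peaks with a score of 200 or more, 409 of 425 (96.2%, interval 94.0 to 97.8%) had a RbΔL/ΔL counterpart, and among such RbΔL/ΔL peaks 262 of 263 (99.6%, interval 97.9 to 99.99%) had a Rb+/+ counterpart. Between 100 and 200 the shares were 48.6% of 615 Rb+/+ peaks and 57.5% of 579 RbΔL/ΔL peaks. Below 60 they were 3.29% of 3525 Rb+/+ peaks (interval 2.73 to 3.93%) and 4.10% of 2050 RbΔL/ΔL peaks (interval 3.28 to 5.05%). These low shares were still above the highest values reached by moving the other list's peaks locally, 0.738% and 1.12%. Overlapping peaks were also wider, with a median of 511.5 bp against 422 bp for the other peaks in Rb+/+ and 429.5 bp against 410 bp in RbΔL/ΔL. In 1047 pairs in which 1 peak met exactly 1 partner, the scores in both lists were correlated across peaks (Spearman's rho 0.75). In the 521 of these pairs with both scores at 100 or more, rho was 0.67. Peaks are not independent replicates, and no p-value is attached to these values. The Rb+/+ peak was the wider of the pair in 723 of the 1047 pairs (69.1%), with median widths of 513 and 429 bp.

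**Figure D1:**
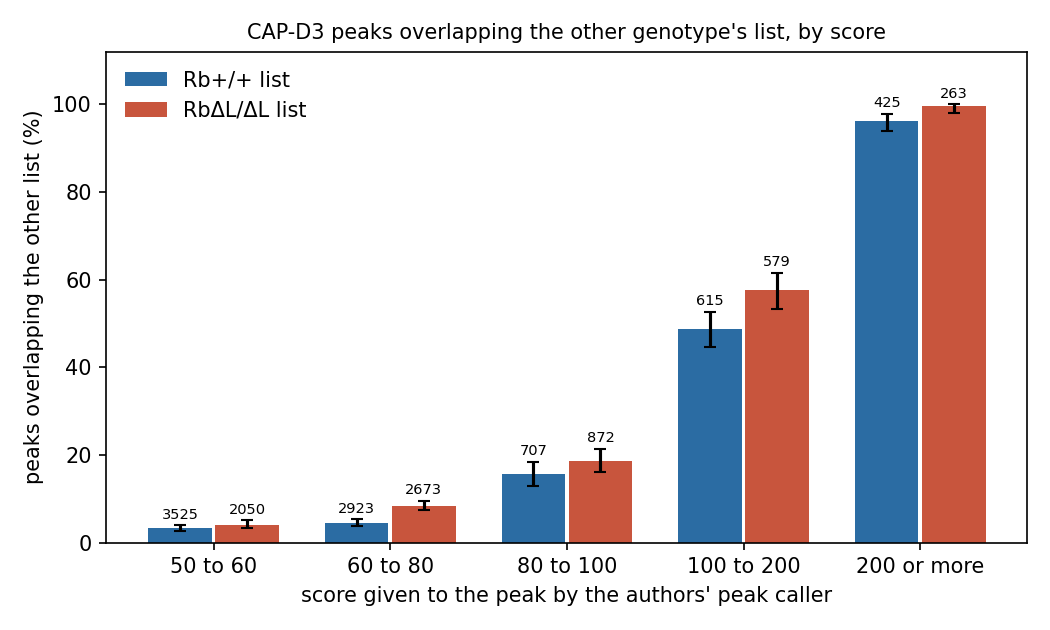
Share of CAP-D3 peaks (%, vertical axis) that overlap a peak of the other genotype's list by at least 1 bp, by the score of the peak (horizontal axis). Blue bars are the Rb+/+ list and red bars the RbΔL/ΔL list, error bars are exact 95% binomial intervals, and the number above each bar is the number of peaks. The shares lie at 3.29% and 4.10% in the lowest band and at 96.2% and 99.6% in the highest.

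The highest-scoring shared site in both lists lay on chromosome 2 at 98506285 to 98507575 in Rb+/+ (score 3227.04) and at 98506287 to 98507577 in RbΔL/ΔL (score 3100). Whether either value is an upper limit of the caller is not known, so the 2 scores do not show which peak was stronger. The other sites among the 5 highest-scoring shared Rb+/+ peaks were chromosome 5 at 124356950 to 124357640 (score 1768.58), chromosome 11 at 98063561 to 98064553 (score 1767.63), chromosome 2 at 98502293 to 98503221 (score 1648.21) and chromosome 17 at 39979884 to 39983687 (score 1618.24). In the RbΔL/ΔL list, these chromosome 2 and chromosome 17 sites filled the top ranks. Next came chromosome 2 at 156005808 to 156006303 (score 1364.53) and chromosome 4 at 126354691 to 126355211 (score 1194.77). Both overlapped Rb+/+ peaks, with scores of 1382.96 and 1389.57 in that list.

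In 3 regions, groups of CAP-D3 peaks lay close together in both genotypes, at similar positions. On chromosome 2, 3 peaks lay between 98502293 and 98507575 in Rb+/+ and 3 between 98502000 and 98507577 in RbΔL/ΔL. At the start of the sequenced part of chromosome 9, 9 Rb+/+ peaks spanned 2999948 to 3036474 and 10 RbΔL/ΔL peaks spanned 2999945 to 3036429, of which 7630 and 9140 bp were covered, and 8 of each overlapped the other list. On chromosome 17, 2 peaks covered 5374 bp between 39979884 and 39985904 in Rb+/+ and 2 covered 5600 bp between 39979893 and 39985877 in RbΔL/ΔL. The chromosome 17 site held the widest peak of each list, 3804 bp in Rb+/+ and 3842 bp in RbΔL/ΔL. Of the 13 one-to-one pairs in these regions, 4 had both edges within 10 bp of each other in the 2 lists, against 2 of the 1034 pairs elsewhere, and the median difference of the more distant edge was 63 bp against 174 bp. These regions were singled out after their values were seen. Without values from the input library, enrichment by the antibody there was not separated from a high level of background.

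**Figure D2:**
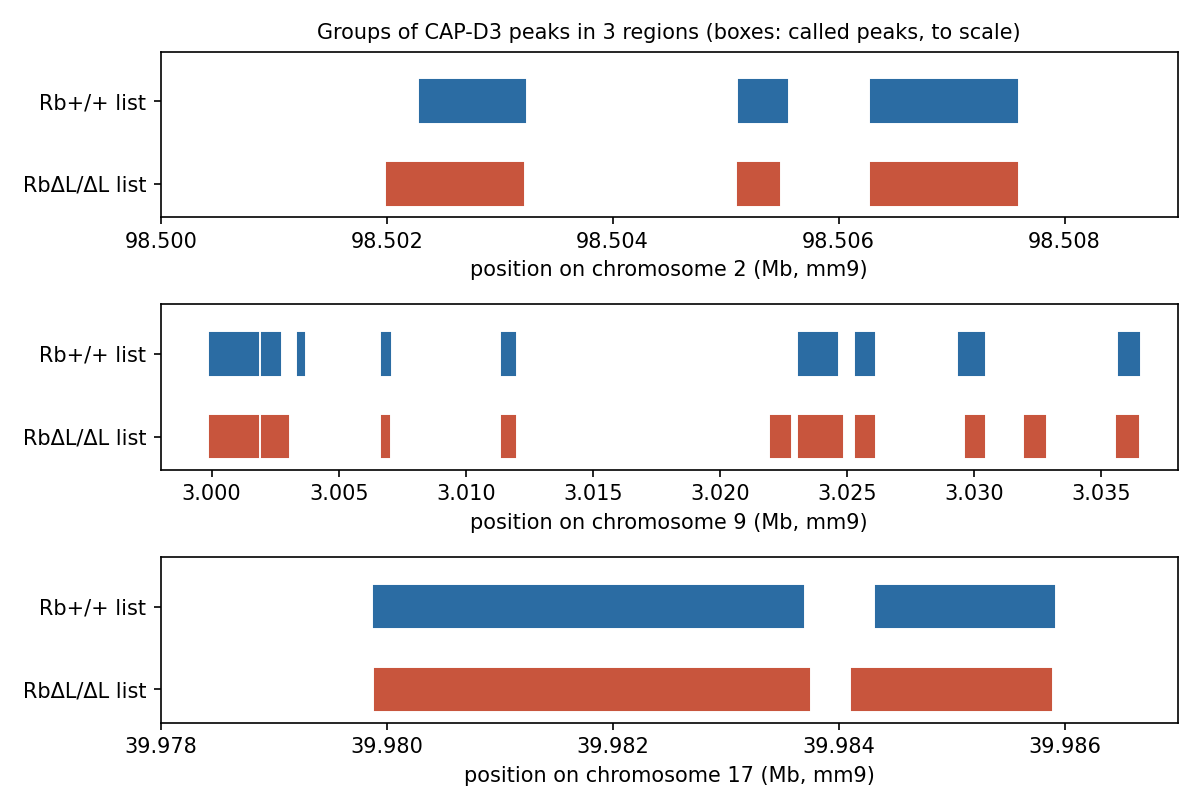
Called CAP-D3 peaks in the regions of chromosomes 2, 9 and 17 that hold groups of peaks, drawn to scale against position (horizontal axis, Mb, mm9). Blue boxes are Rb+/+ peaks and red boxes RbΔL/ΔL peaks. The lists hold 3 and 3 peaks on chromosome 2, 9 and 10 on chromosome 9, and 2 and 2 on chromosome 17, and box height carries no value.

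Some strong peaks were listed in 1 genotype alone. The 5 highest-scoring Rb+/+ peaks with no overlapping RbΔL/ΔL peak lay on chromosome 18 at 81130596 to 81131000 (score 437.8), chromosome 8 at 63966191 to 63966762 (score 309.9) and 73062674 to 73063664 (score 289.08), chromosome 11 at 69793596 to 69793953 (score 282.78), and chromosome 9 at 42913781 to 42914235 (score 260.41). The nearest RbΔL/ΔL peak to the chromosome 18 site was 273 kb away. In all, 16 Rb+/+ peaks with a score of 200 or more had no counterpart, and their nearest RbΔL/ΔL peaks were 15.5 to 736 kb away. Only 1 such RbΔL/ΔL peak had no Rb+/+ counterpart, on chromosome 13 at 32893691 to 32894262 (score 209.18). The next RbΔL/ΔL peaks without a counterpart were on chromosome 4 at 155079053 to 155079459 (score 165.73), chromosome 12 at 88729022 to 88729760 (score 165.49), chromosome 8 at 67144174 to 67144382 (score 160.16) and chromosome 5 at 130731118 to 130731620 (score 154.06). Scores rank peaks only within a list, and a score of 200 took in 425 Rb+/+ but 263 RbΔL/ΔL peaks. Among the 500 highest-scoring peaks of each list, 35 in Rb+/+ and 33 in RbΔL/ΔL had no counterpart. A site missing from a list had no peak above the caller's threshold there, and the signal below the threshold is not known.

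CAP-D3 peaks were densest on chromosomes 11 and 19 and sparsest on the X chromosome in both genotypes. Chromosome 11 carried 5.07 peaks per Mb in Rb+/+ (interval 4.68 to 5.49) and 3.59 in RbΔL/ΔL (interval 3.26 to 3.94), against means of 3.11 and 2.44 over all chromosomes. Chromosome 19 carried 4.48 (interval 3.97 to 5.05) and 3.36 (interval 2.92 to 3.85) peaks per Mb. The X chromosome carried 1.33 (interval 1.16 to 1.51) and 0.924 (interval 0.784 to 1.08). Relative to the autosomes, the density on X was 0.411 in Rb+/+ (interval 0.358 to 0.470) and 0.364 in RbΔL/ΔL (interval 0.308 to 0.427). Among Rb+/+ peaks, this ratio was lower for those with a RbΔL/ΔL counterpart (0.226, interval 0.129 to 0.369, from 16 peaks on X) than for those without (0.439, interval 0.380 to 0.505). In the RbΔL/ΔL list the corresponding ratios lay in the same order, with overlapping intervals. They were 0.226 (interval 0.128 to 0.368, from 16 peaks on X) and 0.391 (interval 0.328 to 0.463). No difference between these ratios was computed in either list. The sex of the cells and their number of X copies were not determined, and densities were not corrected for copy number. The lower density on X can therefore not be read as less CAP-D3 binding per copy. No peak was listed on the Y chromosome or on mitochondrial DNA.

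The share of peaks on each chromosome did not separate the genotypes. For all 20 chromosomes, the interval of the difference in share (Newcombe's method) included 0, and the largest difference, on chromosome 11, was 0.752 percentage points higher in Rb+/+ (interval -0.0934 to 1.59). Densities on the chromosomes ranked alike in both lists (Spearman's rho 0.92 across chromosomes, which are not replicates).

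**Figure D3:**
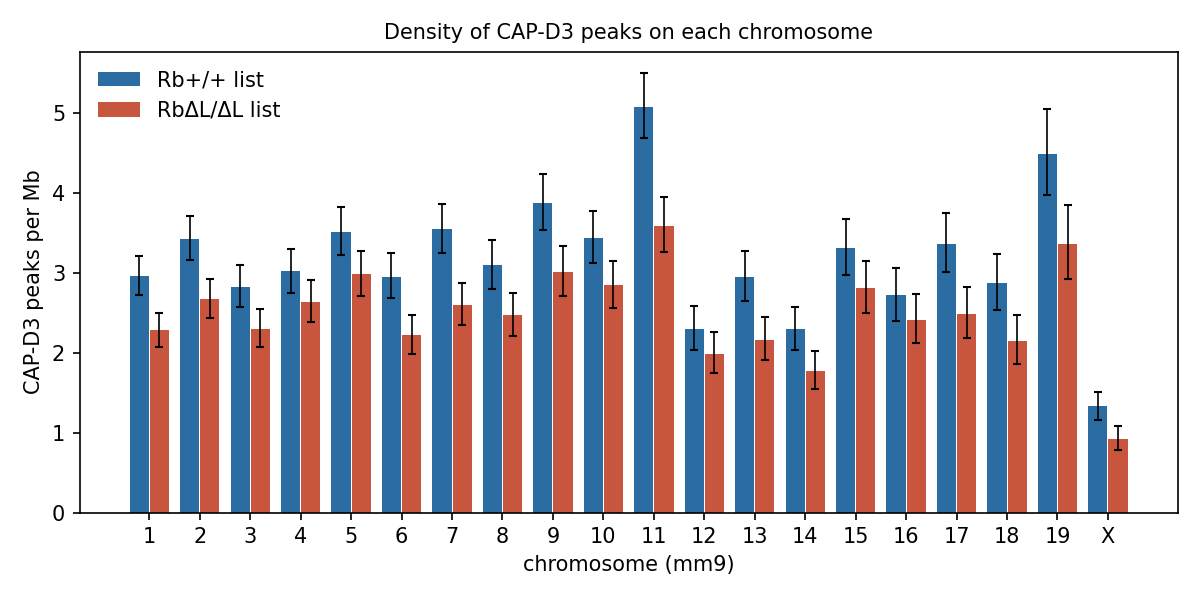
CAP-D3 peaks per Mb (vertical axis) on each mm9 chromosome (horizontal axis), in the Rb+/+ list (blue) and the RbΔL/ΔL list (red), with exact 95% Poisson intervals as error bars. Chromosome 11 is highest, at 5.07 and 3.59, and X is lowest, at 1.33 and 0.924.

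Mouse centromeres lie at the low-coordinate end of each chromosome, and condensin II with the retinoblastoma protein has been studied at the repeats around them. Those satellite arrays are largely missing from the assembly, so only the adjoining sequence was examined. The full length of each zone was counted, without correction for gaps or for sequence to which reads cannot be assigned. On chromosome 14 neither list held a peak before 8655420, and on X neither held one before 5190861. In the first 5 Mb of sequence, peak density was 0.96 times the mean in Rb+/+ (305 peaks, interval 0.857 to 1.07) and 1.04 times the mean in RbΔL/ΔL (260 peaks, interval 0.921 to 1.17). The share of peaks there differed by -0.317 percentage points (Rb+/+ minus RbΔL/ΔL, interval -0.958 to 0.309). At the distal ends, the last 5 Mb held 1.26 times the mean density in Rb+/+ (401 peaks, interval 1.14 to 1.39) and 1.24 times in RbΔL/ΔL (309 peaks, interval 1.11 to 1.38). In RbΔL/ΔL this excess was not separated from the mean in the last 2 Mb (1.09 times, interval 0.898 to 1.31). At a score of at least 100 the distal density was 1.29 times the mean in Rb+/+ (interval 0.969 to 1.68) and 1.26 times in RbΔL/ΔL (interval 0.907 to 1.69), and both intervals included 1. In the first 10 Mb of sequence, the density was 0.829 times the mean in Rb+/+ (interval 0.762 to 0.901, below 1) and 0.926 times in RbΔL/ΔL (interval 0.846 to 1.01). Among peaks with a score of at least 100, the density near the centromeric end was 1.31 times the mean in Rb+/+ (interval 0.990 to 1.71) and 1.56 times in RbΔL/ΔL (interval 1.17 to 2.03), and without the regions of chromosomes 2, 9 and 17 above, it was 1.20 (interval 0.891 to 1.58) and 1.397 (interval 1.03 to 1.85).

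CAP-D3 peaks lay closer together than random placement gives in both genotypes. In Rb+/+, 1392 peaks (16.99%, interval 16.2 to 17.8%) had another peak within 10 kb, against a mean of 6.79% and a highest value of 7.97% in 1000 placements. In RbΔL/ΔL, 768 peaks (11.9%, interval 11.1 to 12.7%) did, against a mean of 5.35% and a highest value of 6.65%. For the 6437 highest-scoring Rb+/+ peaks, as many as the RbΔL/ΔL list holds, the share was 14.2% (interval 13.3 to 15.04%). This was lower than over the full list and still above the RbΔL/ΔL share. That cut dropped only the lowest-scoring Rb+/+ peaks and kept all RbΔL/ΔL peaks. A clustered peak makes its neighbour clustered too, so the intervals of these shares are too narrow to separate the lists. At a score of at least 100, the shares were 3.08% (interval 2.11 to 4.32%) in Rb+/+ and 2.97% (interval 1.93 to 4.35%) in RbΔL/ΔL, with overlapping intervals. The densest megabase in Rb+/+ was 79 to 80 Mb of chromosome 10, with 27 Rb+/+ and 15 RbΔL/ΔL peaks, followed by 5 to 6 Mb of chromosome 19, with 26 and 17. The densest in RbΔL/ΔL was 80 to 81 Mb of chromosome 10, with 21 RbΔL/ΔL and 17 Rb+/+ peaks. The fullest megabase in any random placement held 19 peaks for Rb+/+ and 14 for RbΔL/ΔL.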

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

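Of 68 alternative values for 18 results, 40 stayed close to the reported value and 28 moved. Close meant within 1.5 times for numbers of peaks, within the 95% interval for shares and densities, and within the range of the placements for chance overlap. Leaving out the regions of chromosomes 2, 9 and 17 and the local shift were chosen after seeing the data. With a score minimum of 100 in both lists, 1040 Rb+/+ and 842 RbΔL/ΔL peaks remained, overlap rose to 50.6% and 62.5%, and peaks within 10 kb of another fell to 3.08% and 2.97%. The X share was then 1.92% in Rb+/+ (2.70% over all peaks) and 1.43% in RbΔL/ΔL (2.39%), with wide intervals that include those values. The chromosome 11 share was 9.71% in Rb+/+ (interval 7.98 to 11.7%, against 7.54% over all peaks) and 7.60% in RbΔL/ΔL (6.79%). The chromosome 19 share was 3.37% in Rb+/+ (3.36%) and 4.51% in RbΔL/ΔL (interval 3.21 to 6.14%, against 3.20%). Density near the centromeric end was 1.31 and 1.56 times the mean, or 1.20 and 1.397 without the regions of chromosomes 2, 9 and 17. The interval of the strong peaks lay above 1 in RbΔL/ΔL and reached below 1 in Rb+/+, and over all peaks in the first 5 Mb both included 1. The intervals of the strong peaks overlapped each other, and no difference between the lists was computed at this minimum. The cause of the higher values at this minimum was not tested. Equal list lengths gave an overlap of 15.7% for Rb+/+ and 14.2% clustered Rb+/+ peaks, with the lowest-scoring Rb+/+ peaks dropped. A reciprocal overlap of 50% gave 9.88% and 12.6%, and peaks within 1 kb gave 15.3% and 19.05%. Local shifts gave a chance overlap of 0.393% for Rb+/+ peaks, against 0.223% for uniform placement. A zone of 10 Mb gave 0.829 times the mean at the centromeric end in Rb+/+ (interval 0.762 to 0.901, below 1), and a zone of 2 Mb gave 1.09 times the mean at the distal end in RbΔL/ΔL (interval 0.898 to 1.31, no longer above 1). Clustering within 100 kb was 64.3% and 55.4%, and within 1 kb 4.62% and 3.14%, as the definition of the distance sets. No paired analysis was possible because each genotype has 1 library. For the same reason no library could be left out and no other split of the samples exists. The unknown read depth limits what weak peaks can show. Comparisons with gene features, gene lists and sequence content were not run.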

Other observations

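The tests of overlap by score, of score steps, of edges and of genotype in this part were chosen after seeing the results they measure. The 1 kb distance was chosen before the data were examined, and the bounds it was held to were set after its value was seen. The correlations across megabases were added after the peak lists and the fullest megabases were seen but before any correlation was computed. Peaks of the 2 lists that did not overlap each other still fell in the same neighbourhoods. Across 2589 bins of 1 Mb, the counts of Rb+/+ peaks and RbΔL/ΔL peaks without a counterpart were correlated (Spearman's rho 0.53), above the highest of 1000 circular shifts (0.12). Over all peaks rho was 0.64. Among the fullest megabases, 5 to 6 Mb of chromosome 19 and 79 to 80 Mb of chromosome 10 stood in the first 6 of both lists. In Rb+/+, 69 to 70 Mb of chromosome 11 held 21 peaks, and in RbΔL/ΔL 14. At 137 to 138 Mb of chromosome 5 there were 20 Rb+/+ and 8 RbΔL/ΔL peaks.

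The regional agreement of 0.53 is itself the pattern, so it does not bear on why it exists. A property of the chromatin or sequence that both libraries share stays open as a candidate explanation. Weak peaks at the flanks of strong shared sites were argued against: in the 1883 bins with no overlapping peak, rho was still 0.45, above the highest shift (0.10). Thinly spread CAP-D3 binding and background both stay open too, since no input values and no annotation of this build were used here.

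Why most peaks of each list had no counterpart stays open. Peaks called side by side were argued against as the main cause, since allowing 1 kb raised the Rb+/+ share only to 15.3%. A candidate explanation is that most weak peaks rest on few reads near the calling threshold, but the share with a counterpart at a Rb+/+ score under 60, 0.034 times that at 200 or more, would look alike if weak sites were lost or gained. Loss or gain of CAP-D3 binding with genotype cannot be told apart from chance between libraries, with 1 library per genotype, and this includes the 16 Rb+/+ peaks and 1 RbΔL/ΔL peak with a score of 200 or more.

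The scores were stepped. A score of exactly 64.24 was shared by 318 Rb+/+ peaks and one of exactly 65.68 by 335 RbΔL/ΔL peaks. For each tag number from 3 to 40, the background of a Poisson tail was set to give that score, and the tag number was chosen by how many peaks lay on the 6 further steps it predicts. The chosen tags put 349 Rb+/+ and 538 RbΔL/ΔL peaks on these steps (within 0.015), the next best tag numbers 33 and 30, and 1000 offset ladders at most 21 and 17. These scores are consistent with tails beyond 6 tags over a background of 0.431 in Rb+/+ and beyond 5 tags over 0.249 in RbΔL/ΔL, a background 1.73 times higher in Rb+/+ if both scores have this form. Peaks at exactly the most frequent score or within 0.015 of the 6 further steps made up 8.14% of the Rb+/+ and 13.6% of the RbΔL/ΔL list. The further steps all lay above the most frequent score, and steps below it were not counted. The steps describe how scores form, not why a peak has no counterpart.

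For the shares below, peaks were counted within 0.015 of each score. The share of Rb+/+ peaks with a RbΔL/ΔL counterpart was 1.84% of 326 peaks at the most frequent score, 64.24. On the higher steps it was 3.59% of 195 at 76.95, 10.2% of 88 at 90.17, 0 of 39 at 103.84, 26.7% of 15 at 117.93, 6 of 10 at 132.39 and 2 of 2 at 147.19. The 0 of 39 allows a share of up to 7.69% by the limit of 3 counts, and up to 9.03% by the exact interval. In RbΔL/ΔL the share was 9.23% of 336 peaks at the most frequent score, 65.68. On the higher steps it was 6.83% of 249 at 80.18, 14.3% of 140 at 95.26, 20.5% of 83 at 110.84, 28.9% of 38 at 126.88, 13 of 20 at 143.33 and 7 of 8 at 160.16.

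The groups of peaks on chromosomes 2, 9 and 17 lie at positions known in the field as assembled copies of satellite and ribosomal DNA, which stand for many copies in the genome. That identity was not checked against an annotation of this build. A candidate explanation is that their edges are fixed by the reference sequence, where collapsed repeats gather reads from any library. The median edge difference there was 63 bp, against 174 bp for other shared pairs, a ratio of 0.36 that lies between the bounds set for and against this. CAP-D3 binding at repeats, the other open explanation, cannot be told apart from it, because 0 files of the input library were used. Peaks in these regions were called in RbΔL/ΔL as well as in Rb+/+ cells, and their heights cannot be compared between lists.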
